A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

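RNA of 8 samples of Saccharomyces cerevisiae was measured on Affymetrix Yeast Genome 2.0 arrays. The labels assign 2 arrays to each of 4 groups: strain NBRC 0224 and strain NFRI 3145, each without acetic acid (0% AcOH) and under 0.6% acetic acid (0.6% AcOH). Per the labels, polyA RNA was prepared after a hot phenol extraction and labelled with biotin by the manufacturer's manual. The submitters' processing notes name the Affymetrix software GCOS, with no version and no target value. The deposited values are linear probe set signals in intensity units, 1 value per probe set and array. Each array's mean after trimming 2% from each end lay between 499.3 and 499.4, so the deposited arrays had been scaled to a common trimmed mean. They were not log transformed and not quantile normalized. The original probe-level images were not used here.

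The array holds 10928 probe sets, of which 213 are controls, 7244 carry 1 gene symbol, 1 carries several and 3470 carry none. S. cerevisiae genes were recognised through the gene table of the R64 assembly, which also gave 12 updated symbols, gene spans and gene neighbours. This left 5498 probe sets of 5449 S. cerevisiae genes. The other 1746 probe sets with a symbol belong to Schizosaccharomyces pombe, and their 95th percentile on an array was taken as that array's background (31.5 to 43.9 intensity units). A gene was tested when its signal exceeded background on at least 2 of the 8 arrays, which held for 3879 genes and left out 1570. For the 47 genes with more than 1 probe set, the probe set with the highest mean log2 signal was used. Of the tested genes, 93 are measured by probe sets named _s_at or _x_at, which can hybridise with related transcripts. The probes follow the reference strain, and they were not compared with the sequences of these 2 strains.

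Log2 signals of all 8 arrays were fitted with limma 3.58.1 in R 4.3.3 as 4 group means, with eBayes(trend = TRUE) and Benjamini-Hochberg adjustment over the 3879 genes. The fit had 4 residual degrees of freedom, and 11.3 after moderation. A gene was called at an adjusted p under 0.05. The 5 comparisons were the response to acetic acid in each strain, the difference of the responses (NFRI 3145 minus NBRC 0224), and the strain difference (NFRI 3145 minus NBRC 0224) at 0% AcOH and at 0.6% AcOH. Log2 changes are given with the standard error (SE) of the fit and compare 2 arrays with 2. Where both arrays of a group lay below background, the fold was computed against the background and is written as at least that fold. Where 1 array of a group lay below background, the bound was computed with that array raised to its background. Signals above 10000, a cut-off set here and not tested, were taken as near the top of the scale, where a change can be compressed. The fitted change of a gene with such a group mean may therefore be too small in size. This holds in the report for ARN1 and MMP1 in NBRC 0224, AHP1 in NFRI 3145, HSP10 in both, GLK1, HTA1, FIT2, RPS28A, RPL43B and PMA1. No fold is given where a bound against background is 1 or where both groups lay below background. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

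Gene lists for 39 pathways and regulons were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the 39 lists and called at an adjusted p under 0.05. Beside each called list stand the members called over all genes, the members called with p adjusted over the list alone, and the camera result with an estimated correlation. Medians of a list are of log2 changes. Groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes, in each comparison, the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap. For the difference of the responses it takes the 8 largest in each direction of all called genes. It adds up to 3 called members of each called list with the smallest p, and HAA1, WAR1, PDR12, FPS1, PMA1 and HSP30 whatever their values. The report names mainly the genes that stayed called whichever array was left out, and gives the others as counts. Of the 155 called results of this rule, 96 stayed called whichever array was left out.

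The steps were tested on simulated data with 3879 genes, of which 200 changed, in 20 runs. In the response of NBRC 0224, 32.7% of genes changed 2-fold and 73.6% of genes changed 4-fold were recovered, and in the response of NFRI 3145 32.7% and 71.4%. For the strain difference these shares were 33.6% and 70.0% at 0% AcOH, and 34.4% and 71.2% at 0.6% AcOH. For the difference of the responses they were 14.7% and 50.1%. False calls made up 3.18% to 4.85% of the calls in these simulated data. A list of 25 genes, each shifted 2-fold, was called in 20 of 20 runs of each comparison. The simulated genes were drawn independently, so these runs do not test the calls of lists with correlated genes or smaller shifts. Each gene had the same spread in all 4 groups, and no array as a whole was shifted. The shares of recovered and false calls hold for that setting and are not shown for the measured arrays.

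The alternatives tried were no filter on low signal, a filter requiring signal above background on all 8 arrays, quantile normalization, median centring, a floor at the median S. pombe signal, and a pseudocount of 39.4. Others were a variance model without trend, a robust variance, only the groups compared, a block for replicate number, a change of at least 2-fold, an adjusted p under 0.01, every probe set by itself, no cross-hybridising probe sets, and each array left out in turn. For lists, an estimated correlation and the rotation test fry were tried. Removal of each array's trend with gene length was chosen after the data were seen. It used gene spans, which include introns, so it can remove too little from ribosomal protein genes with introns, and members with a span of at most 600 nucleotides were also taken alone. With an array left out, the lone array of its group is assumed to vary like the other groups. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, and that spread could be technical.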

Results

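Transcript levels were measured in 2 strains of Saccharomyces cerevisiae, NBRC 0224, which the labels call sensitive to acetic acid, and NFRI 3145, which they call tolerant. Cells of each strain were sampled at 30 °C without acetic acid (0% AcOH) or after 30 min with 0.6% acetic acid (0.6% AcOH), with 2 arrays in each of the 4 groups. The labels give a time for the 0.6% AcOH samples only. A response to acid is here the difference between the 2 acid levels. It cannot be told apart from effects of time or handling. The series compares the profiles of the 2 strains in order to pick a gene related to tolerance. The share of the 3879 tested genes above background ran from 70.4% on NFRI 3145 0.6% AcOH replicate 1 to 91.3% on NBRC 0224 0% AcOH replicate 2, and the median signal of tested genes from 115 to 189 intensity units. Replicates correlated at r of 0.968 to 0.981 across genes, which are not independent replicates. The share of genes more than 2-fold apart between replicates was 5.47% in NBRC 0224 at 0% AcOH and 12.8% at 0.6% AcOH, and 8.48% and 11.3% in NFRI 3145. All 4 spiked control transcripts read highest on NBRC 0224 0.6% AcOH replicate 2. With 2 arrays a group, the number of arrays limits the precision of every value.

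In NBRC 0224, some genes of iron uptake, chaperones and glucose synthesis were higher at 0.6% than at 0% AcOH, and some of purine synthesis lower. No list call in this strain held with an estimated correlation. The largest rise was that of FRE7, a metalloreductase gene, at 4.36 ± 0.26 on the log2 scale (SE, n = 2 arrays per group), from a mean signal of 195 to 3893. FBP1, which encodes the gluconeogenic fructose-1,6-bisphosphatase, rose by 4.01 ± 0.39, from 58.8 to 1022. Among the falls, IZH4, a membrane protein gene of the zinc regulon, was at least 7.66-fold lower from 297, and the small reading frame YBR182C-A at least 12.2-fold lower from 702, each with 1 array below background. YMR105W-A was at least 9.27-fold lower.

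The iron regulon of Aft1, the activator of iron uptake genes, had 9 of 27 tested members higher and none lower (median 0.45, 11 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.5e-07, and adjusted p = 0.092 with an estimated correlation). FET3, the multicopper oxidase of high-affinity iron uptake, rose by 3.21 ± 0.24, from 443 to 3982. ARN1, a siderophore transporter, rose by 3.02 ± 0.20, and FRE4, a ferric reductase, by 2.79 ± 0.21. Of the chaperones under Hsf1, the heat shock factor, 7 of 16 rose and none fell (median 0.87, 10 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.5e-07, and adjusted p = 0.092 with an estimated correlation). HSC82, an Hsp90 chaperone, rose by 1.45 ± 0.13, from 3393 to 9310, HSP26, a small heat shock protein, by 2.21 ± 0.22, and HSP10, the mitochondrial co-chaperonin, by 1.48 ± 0.16. In the list of oxidative stress genes (Yap1/Skn7), 6 of 25 rose and 1 fell (median 0.19, 8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0026, and adjusted p = 0.19 with an estimated correlation). The median was 0.29 without NBRC 0224 0.6% AcOH replicate 2. The peroxiredoxin gene AHP1 rose by 1.45 ± 0.16 and the thioredoxin gene TRX2 by 1.27 ± 0.17. Of the purine synthesis genes, 7 of 12 fell and none rose (median −1.20, 0 higher and 10 lower adjusted over the list alone, camera adjusted p = 6.8e-07, and adjusted p = 0.17 with an estimated correlation). ADE1, an enzyme of the purine pathway, changed by −1.85 ± 0.20, from 3356 to 926.

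The other 7 called lists of NBRC 0224 each lost the call when 1 or more arrays were left out. In acetate use, glyoxylate cycle and gluconeogenesis, 5 of 20 rose and 1 fell (median 0.61, 6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.48 with an estimated correlation), with PCK1, the entry enzyme of gluconeogenesis, up by 2.82 ± 0.26 and YAT1, a carnitine acetyltransferase, by 2.09 ± 0.30. Without NBRC 0224 0.6% AcOH replicate 1 the list's median was 0.21 and its adjusted p 0.16, and without replicate 2 the median was 0.94. Of the general stress (Msn2/4) genes, 8 of 28 rose and none fell (median 0.20, or 0.13 with bounds, 8 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0044, and adjusted p = 0.19 with an estimated correlation), and the adjusted p was 0.069 without NBRC 0224 0.6% AcOH replicate 1. The Msn2/4 median was 0.44 without NBRC 0224 0% AcOH replicate 1 and 0.39 without NBRC 0224 0.6% AcOH replicate 2. In sulfur and methionine metabolism, 4 of 22 rose, among them the S-methylmethionine permease gene MMP1 by 1.33 ± 0.16, and 1 fell (median 0.32, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0084, and adjusted p = 0.48 with an estimated correlation). Without NBRC 0224 0% AcOH replicate 1 the median of that list was 0.18 and its adjusted p 0.11. Of the amino acid synthesis genes under Gcn4, 4 of 43 fell and 1 rose (median −0.21, or −0.20 with bounds, 1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.022, and adjusted p = 0.51 with an estimated correlation), with the arginine synthesis gene ARG1 at −1.89 ± 0.23. This call ended without NBRC 0224 0% AcOH replicate 2 (adjusted p = 0.12) and under median centring.

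Among the cytosolic ribosomal proteins, 5 of 128 rose, with RPS28A up by 1.14 ± 0.14, and 3 fell (median 0.14, 5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0014, and adjusted p = 0.59 with an estimated correlation). The call ended under quantile normalization and without NBRC 0224 0% AcOH replicate 2 (median 0.051, adjusted p = 0.38), and the median was 0.090 without NBRC 0224 0.6% AcOH replicate 2. In the respiratory chain and ATP synthase, 2 of 33 rose and none fell (median 0.14, or 0.13 with bounds, 5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.047, and adjusted p = 0.59 with an estimated correlation). Its adjusted p was 0.38 without NBRC 0224 0% AcOH replicate 2, 0.24 without NBRC 0224 0.6% AcOH replicate 1, 0.056 without NFRI 3145 0% AcOH replicate 1 and 0.051 without NFRI 3145 0% AcOH replicate 2. The median of this list was 0.23 and 0.065 without NBRC 0224 0% AcOH replicates 1 and 2, and 0.24 without NBRC 0224 0.6% AcOH replicate 2. Glycolysis and fermentation was called higher with none of its 16 members called (median 0.16, 0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.026, and adjusted p = 0.72 with an estimated correlation). Its median was −0.01 after quantile normalization, and its adjusted p was 0.11 without NBRC 0224 0% AcOH replicate 1 and 0.66 without NBRC 0224 0.6% AcOH replicate 2. The glycolysis median was 0.30 and 0.026 without NBRC 0224 0.6% AcOH replicates 1 and 2. The Haa1 weak-acid regulon, which answers to weak organic acids, was not called (0 of 14 higher and 1 lower; camera adjusted p = 0.57).

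By limma, 140 genes were called higher and 186 lower in NBRC 0224, of which 90 and 140 changed at least 2-fold. Quantile normalization gave 181 higher and 152 lower, and median centring 198 and 128, so the balance of the directions depends on the scaling. Both scalings move the median log2 change of all tested genes, from −0.11 in the deposited scaling to −0.01 and 0.05. The counts were 44 and 32 without NBRC 0224 0% AcOH replicate 1, 59 and 44 without NBRC 0224 0% AcOH replicate 2, and 325 and 425 without NBRC 0224 0.6% AcOH replicate 1. Of the 8 rises and 8 falls named by size, 4 and 4 stayed called whichever array was left out.

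In NFRI 3145, some iron uptake and chaperone genes also rose, together with some genes of respiration. A regulator of the weak-acid response and some genes of purine synthesis fell. No list call in this strain held with an estimated correlation. SSA1, a cytosolic Hsp70 chaperone gene, rose by 3.74 ± 0.30 on the log2 scale (SE, n = 2 arrays per group), from 153 to 2008, and the low-affinity glucose transporter gene HXT1 by 2.91 ± 0.17, from 847 to 6353. CTR3, a copper transporter gene, was at least 5.82-fold higher. HAA1, the activator of the weak-acid response, was at least 4.24-fold lower from 188, with 1 array below background. YET1, a gene of the endoplasmic reticulum, was at least 40.8-fold lower from 1708, and YMR105W-A at least 21.9-fold lower. MTH1, a regulator of glucose transporter genes, was at least 2.47-fold lower, and MPD2, a protein disulfide isomerase gene, at least 3.05-fold lower.

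Of the iron (Aft1) regulon, 10 of 27 rose and none fell (median 0.56, or 0.37 with bounds, 10 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.3e-06, and adjusted p = 0.082 with an estimated correlation). FET3 rose by 3.40 ± 0.24, from 482 to 5108, the siderophore transporter gene SIT1 by 3.08 ± 0.24 and ARN1 by 2.30 ± 0.20. Of the Hsf1 chaperones, 8 of 16 rose and none fell (median 0.82, 11 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.3e-08, and adjusted p = 0.082 with an estimated correlation), with HSP26 up by 2.23 ± 0.22 and HSP10 by 1.49 ± 0.16. In the TCA cycle, 5 of 15 rose and none fell (median 0.52, 5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0025, and adjusted p = 0.32 with an estimated correlation). The isocitrate dehydrogenase subunit IDH2 rose by 1.67 ± 0.21, from 251 to 797, and the aconitase ACO1 by 0.95 ± 0.15. Of the respiratory chain and ATP synthase, 6 of 33 rose and none fell (median 0.36, 6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0027, and adjusted p = 0.38 with an estimated correlation), with the cytochrome c gene CYC1 up by 1.96 ± 0.22. The median of that list was 0.21 without NFRI 3145 0.6% AcOH replicate 2. In the oxidative stress list, 7 of 25 rose and 1 fell (median 0.47, 10 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.4e-04, and adjusted p = 0.20 with an estimated correlation), with AHP1 up by 1.21 ± 0.16.

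Of the purine synthesis genes in NFRI 3145, 5 of 12 fell and none rose (median −0.70, 0 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0025, and adjusted p = 0.32 with an estimated correlation), with ADE1 at −1.92 ± 0.20 and ADE8 at −1.27 ± 0.20. Of the Haa1 weak-acid regulon, 4 of 14 fell and none rose (median −0.86, or −0.63 with bounds, 0 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.65 with an estimated correlation). This list kept its call whichever array was left out, while its difference between the 2 responses was not called (camera adjusted p = 0.21). Of the zinc (Zap1) regulon, 5 of 13 fell and none rose (median −0.39, 0 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.38 with an estimated correlation), and the adjusted p was 0.14 without NFRI 3145 0.6% AcOH replicate 2 and the median −0.63 without NFRI 3145 0% AcOH replicate 1. Under median centring the zinc median was −0.15, with 4 members lower. FET4, a low-affinity iron and zinc transporter gene of that regulon, changed by −1.32 ± 0.22. Of the general stress (Msn2/4) genes, 8 of 28 fell and 1 rose (median −0.61, or −0.46 with bounds, 2 higher and 13 lower adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.31 with an estimated correlation). The adjusted p of this list was 0.064 without NFRI 3145 0% AcOH replicate 1 and 0.094 without NFRI 3145 0% AcOH replicate 2 (median −0.35), and the call ended among genes above background on all 8 arrays.

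By limma, 148 genes were called higher and 375 lower in NFRI 3145, of which 69 and 316 changed at least 2-fold. Quantile normalization gave 198 and 280, and median centring 335 and 285, with the median change of all genes at −0.07, 0.07 and 0.16 in the deposited, quantile and median scalings. Leaving out an array moved the 148 to 249 without NBRC 0224 0.6% AcOH replicate 1 and 251 without NBRC 0224 0.6% AcOH replicate 2. It became 56 without NFRI 3145 0% AcOH replicate 2, 54 without NFRI 3145 0.6% AcOH replicate 1 and 42 without NFRI 3145 0.6% AcOH replicate 2. The 375 became 184 without NFRI 3145 0% AcOH replicate 1, 126 without NFRI 3145 0% AcOH replicate 2 and 227 without NFRI 3145 0.6% AcOH replicate 1. Of the 8 rises and 8 falls named by size, 6 and 4 stayed called whichever array was left out.

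Genes such as FET3, ARN1, HSP26, HSP10, AHP1 and ADE1 responded in the same direction in both strains. In all, 42 genes were higher in both, against 5.34 by chance from the numbers of calls, and 102 were lower in both, against 18. A further 7 genes were called in opposite directions. Across the 3879 genes the 2 responses correlated at r = 0.42, and across the 698 genes called in either strain at r = 0.59, where 79.8% changed in the same direction. These are correlations across genes, which are not independent replicates, and the 2 responses share no array. The 144 shared calls became 41 without NBRC 0224 0% AcOH replicate 1, 51 without NBRC 0224 0% AcOH replicate 2 and 224 without NBRC 0224 0.6% AcOH replicate 1. They became 80 and 72 without NFRI 3145 0% AcOH replicates 1 and 2, and 85 and 89 without NFRI 3145 0.6% AcOH replicates 1 and 2.

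**Figure D1:**
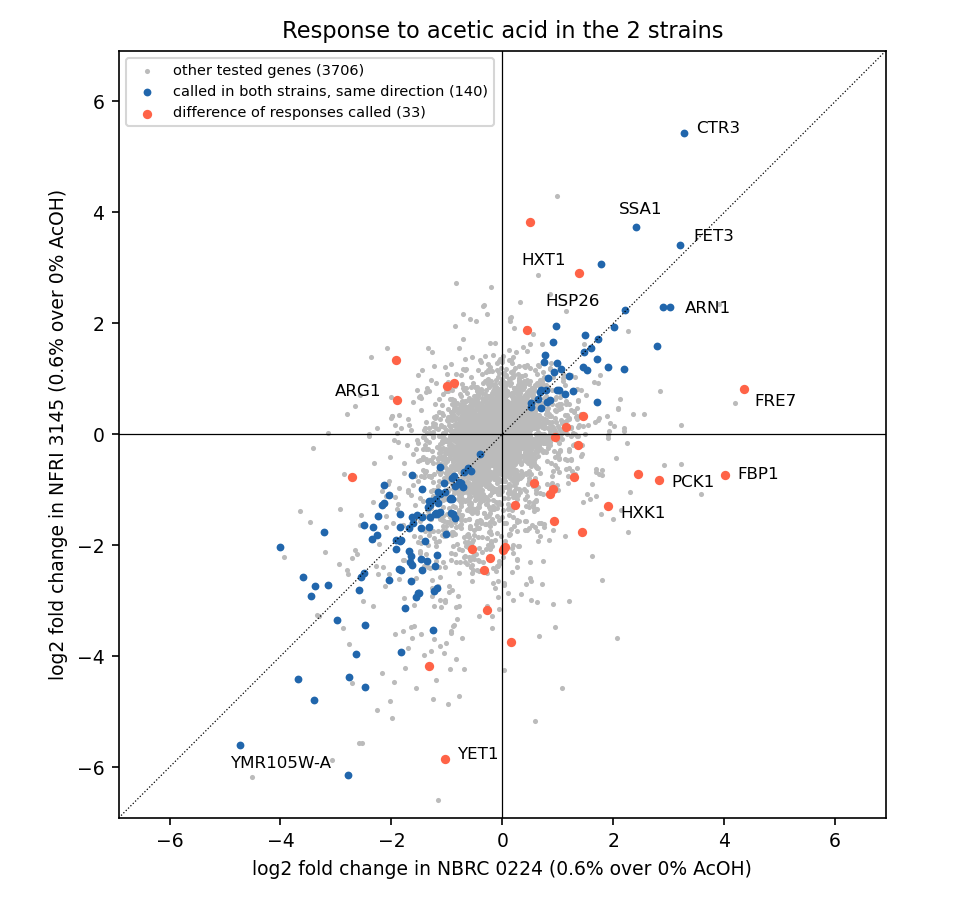
Each point is 1 of the 3879 tested genes, with the log2 change under 0.6% acetic acid in NBRC 0224 on the x axis and in NFRI 3145 on the y axis, and colours mark the genes called in both strains in the same direction and the 33 genes whose responses differed. FBP1, PCK1 and FRE7 were called higher in NBRC 0224 only, and FET3 lies near equal rises in both strains.

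YET1, the glucose synthesis genes FBP1 and PCK1, and the metalloreductase gene FRE7 separated the responses of the 2 strains. FBP1 rose from 58.8 to 1022 in NBRC 0224 but went from 169 to 102 in NFRI 3145 (difference of the log2 changes −4.74 ± 0.55, SE, n = 2 arrays per group, adjusted p = 0.0028). PCK1 rose from 194 to 1402 in NBRC 0224 and went from 195 to 109 in NFRI 3145 (difference −3.65 ± 0.37, adjusted p = 0.0011). FRE7 went from 195 to 3893 and from 126 to 220 (difference −3.55 ± 0.37, adjusted p = 0.0011). YET1 went from 944 to 474 in NBRC 0224 and from 1708 to 30.0, which is below background, in NFRI 3145 (fitted difference −4.81 ± 0.41, adjusted p = 4.1e-04). These 4 genes were the only ones of the 16 named by size in this comparison that stayed called whichever array was left out. ARG1, an enzyme of arginine synthesis, fell from 740 to 198 in NBRC 0224 and went from 502 to 776 in NFRI 3145 (difference 2.51 ± 0.32, adjusted p = 0.0041), and its adjusted p was 0.057 without NBRC 0224 0% AcOH replicate 1.

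Of the general stress (Msn2/4) genes, 3 of 28 had a called difference, all lower in NFRI 3145 (median −1.23, 0 higher and 9 lower adjusted over the list alone, camera adjusted p = 2.8e-06, and adjusted p = 0.14 with an estimated correlation). The 3 were the glucokinase gene GLK1 (−1.45 ± 0.22), the hexokinase gene HXK1 (−3.19 ± 0.50) and the stress gene DDR2 (−3.20 ± 0.53 as fitted, and −2.70 with its 2 arrays below background raised to it), each of which lost the call without NBRC 0224 0% AcOH replicate 1 (adjusted p = 0.097, 0.12 and 0.11) and without replicate 2 of NBRC 0224 0% AcOH or of NFRI 3145 0% AcOH. GLK1 and HXK1 also lost it without NFRI 3145 0.6% AcOH replicate 2. HXK1 went from 168 to 668 in NBRC 0224 and from 374 to 157 in NFRI 3145. In acetate use, glyoxylate cycle and gluconeogenesis, 2 of 20 had a called difference, FBP1 and PCK1 (median −1.37, 2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.67 with an estimated correlation). Without NBRC 0224 0.6% AcOH replicate 1 the median of that list was −0.83 and its adjusted p 0.15. The amino acid synthesis (Gcn4) list was higher in the difference with 1 of 43 members called, ARG1 (median 0.39, 2 higher and 0 lower adjusted over the list alone, camera adjusted p = 3.2e-04, and adjusted p = 0.67 with an estimated correlation). Its median was 0.25 without NBRC 0224 0.6% AcOH replicate 2.

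By limma, 8 genes had a higher and 25 a lower response in NFRI 3145, each with a difference of at least 2-fold. The split was 15 and 36 after quantile normalization and 19 and 21 after median centring. The counts were 0 and 5 without NBRC 0224 0% AcOH replicate 1, where limma put 161 genes with a positive difference at an unadjusted p under 0.05, 2 and 8 without NBRC 0224 0% AcOH replicate 2, and 169 and 174 without NBRC 0224 0.6% AcOH replicate 1. Without NBRC 0224 0.6% AcOH replicate 2, 43 genes had a lower response. Without NFRI 3145 0% AcOH replicate 1, 19 had a higher response. The counts were 5 and 6 without NFRI 3145 0% AcOH replicate 2 and 2 and 12 without NFRI 3145 0.6% AcOH replicate 1, and 3 genes were higher without NFRI 3145 0.6% AcOH replicate 2. The 3 called lists became 5 without NFRI 3145 0.6% AcOH replicate 1. The ratio of 3′ to 5′ signal of the control gene TDH1 moved with acid, from 1.59 and 2.07 to 2.65 and 5.11 on the NBRC 0224 arrays and from 7.68 and 8.14 to 20.1 and 26.5 on the NFRI 3145 arrays. The 3′ signal of TDH1 at 0% AcOH lay above 10000 in both strains, so those ratios can be too small. The ratios of RIP1 and WBP1 moved less, from 1.71 and 1.94 to 1.80 and 2.01 and from 3.36 and 3.82 to 4.02 and 4.39 in NBRC 0224, and from 3.64 and 3.73 to 3.58 and 4.81 and from 8.86 and 9.37 to 9.38 and 9.92 in NFRI 3145. With each array's length trend removed, 12 genes had a higher and 23 a lower response.

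**Figure D2:**
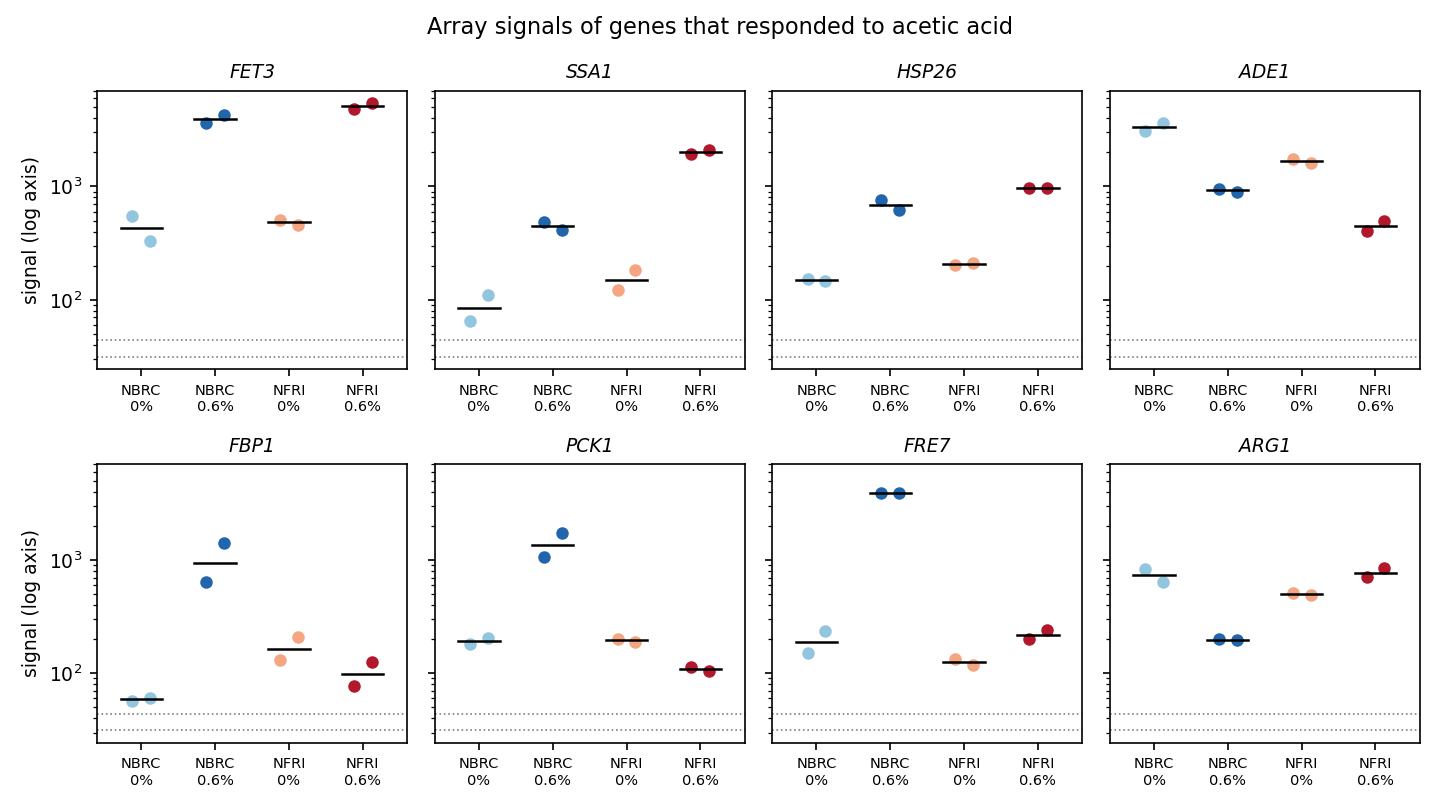
Signal in intensity units on a log axis for FET3, SSA1, HSP26, ADE1, FBP1, PCK1, FRE7 and ARG1, with 1 point per array, a bar at the geometric mean of the 2 arrays of each group, and dotted lines at the lowest and highest background (31.5 and 43.9). FET3 rose in both strains, and FBP1, PCK1 and FRE7 were called higher in NBRC 0224 only.

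Without acetic acid, many ribosomal protein genes were higher and many genes of efflux transporters lower in NFRI 3145 than in NBRC 0224. Both list calls ended with an estimated correlation, and that of the efflux transporters also with the length trend removed. FIT2, a cell wall protein that binds siderophores, was 5.99 ± 0.24 higher on the log2 scale (SE, n = 2 arrays per group). Its mean signals were 220 in NBRC 0224 and 13878 in NFRI 3145, which is near the top of the scale, so this fitted value may be too small. MAL33, an activator of maltose genes, was at least 44.0-fold higher, and AGP3, an amino acid permease gene, at least 3.53-fold higher. DAK2, a dihydroxyacetone kinase gene, was at least 3.81-fold higher and ZNF1, a regulator of respiratory growth, at least 2.82-fold higher. FEX2, a fluoride exporter gene, was at least 111-fold lower, REE1, a gene linked to enolase regulation, at least 103-fold lower, and GDH2, the NAD-dependent glutamate dehydrogenase gene, at least 25.1-fold lower. The asparaginase gene ASP3-1 was at least 336-fold lower and the metallothionein gene CUP1-1 at least 9.58-fold higher, both by probe sets that can cross-hybridise. The bound of CUP1-1 rests on NFRI 3145 arrays far apart (mean 362, standard deviation 206). Of the 8 genes named by size in each direction, 8 and 8 stayed called whichever array was left out.

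Of the cytosolic ribosomal proteins at 0% AcOH, 86 of 128 were higher and 6 lower in NFRI 3145 (median 0.74, 88 higher and 6 lower adjusted over the list alone, camera adjusted p = 2.9e-16, and adjusted p = 0.58 with an estimated correlation). The median was 0.58 after quantile normalization and 1.15 after median centring. RPS28A was 3.75 ± 0.14 higher (1149 and 15497), RPL43B 3.67 ± 0.15 higher (1128 and 14376) and RPL37A 3.89 ± 0.19 higher (443 and 6604). The values of RPS28A and RPL43B may be too small, because their signal in NFRI 3145 lay above 10000. The strain difference also fell with gene length, with a Spearman correlation of −0.31 across 3751 other genes, and the median was 0.62 for 608 genes of at most 600 nucleotides against −0.25 for 3143 longer genes. The ratios of 3′ to 5′ signal of RIP1 and WBP1, which carry probe sets at both ends, were 3.58 to 4.81 and 8.86 to 9.92 on the NFRI 3145 arrays against 1.71 to 2.01 and 3.36 to 4.39 on the NBRC 0224 arrays. With each array's length trend removed, the ribosomal list stayed called with a median of 0.38. Of the drug and acid efflux transporters, 11 of 18 were lower and none higher (median −1.36, 0 higher and 12 lower adjusted over the list alone, camera adjusted p = 6.0e-04, and adjusted p = 0.58 with an estimated correlation). The polyamine and acid exporter TPO4 was −3.74 ± 0.23 apart (9608 and 719), SGE1 −3.56 ± 0.23 apart (4386 and 380), and AZR1, a transporter linked to azole and acetic acid resistance, at least 57.7-fold lower. With the length trend removed, the efflux list was not called (adjusted p = 0.089).

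By limma, 819 genes were higher and 1130 lower in NFRI 3145 at 0% AcOH, of which 543 and 950 differed at least 2-fold. The split was 1049 and 1008 after quantile normalization and 1347 and 840 after median centring, with the median difference of all genes at −0.06, 0.05 and 0.35, so which direction held more genes depends on the scaling. Leaving out an array kept each count within 1.5 times its value. In 330 of the called genes a group lay below background, where a sequence that the probes do not match would give the same value as an absent transcript.

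**Figure D3:**
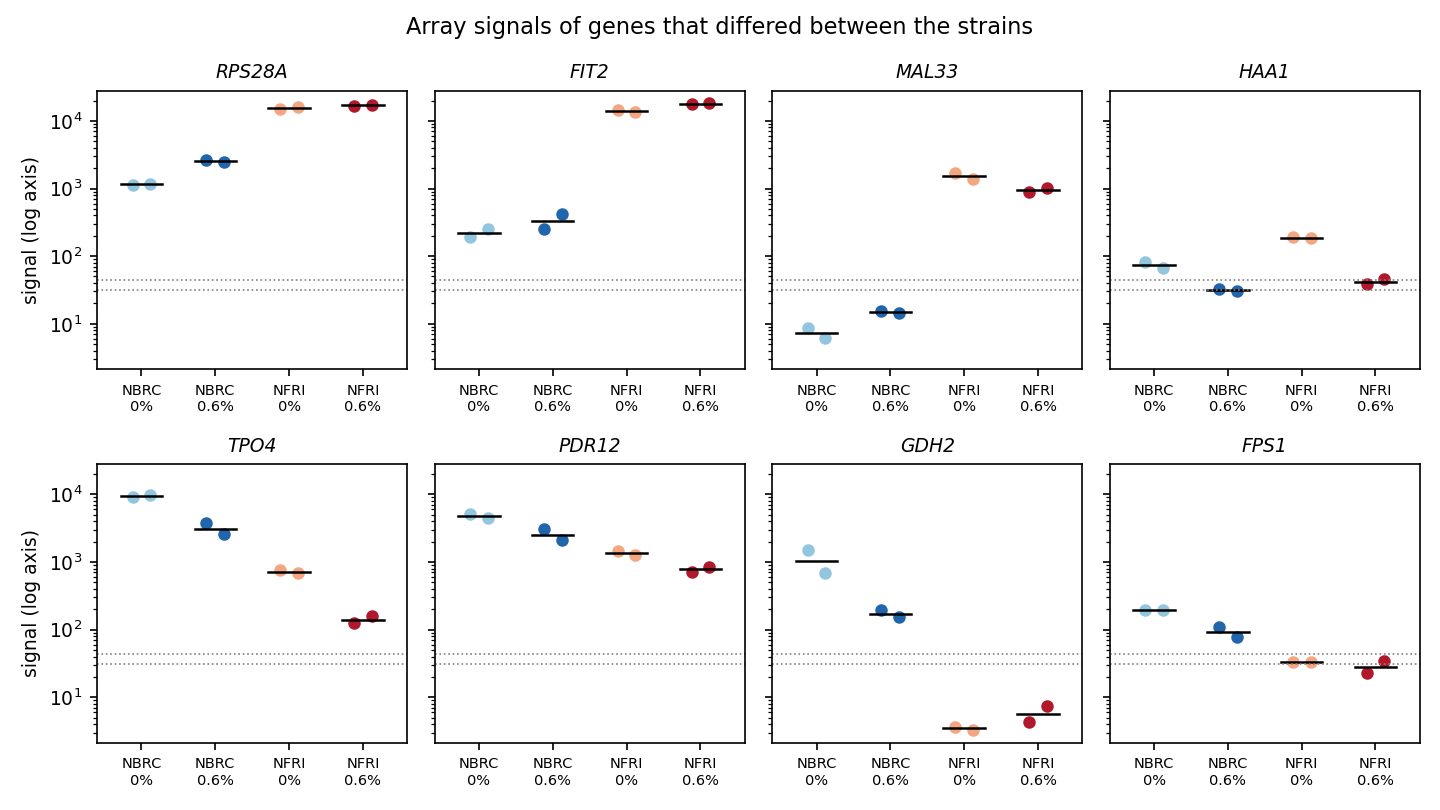
Signal in intensity units on a log axis for RPS28A, FIT2, MAL33, HAA1, TPO4, PDR12, GDH2 and FPS1, with 1 point per array, a bar at the geometric mean of the 2 arrays of each group, and dotted lines at the lowest and highest background (31.5 and 43.9). FIT2 lies at 220 and 13878 in the 2 strains at 0% AcOH, TPO4 at 9608 and 719, and the NFRI 3145 arrays of GDH2 and FPS1 lie below background.

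Under 0.6% acetic acid 514 genes were higher and 863 lower in NFRI 3145 that had the same call at 0% AcOH, and 11 were called in opposite directions at the 2 levels. From the numbers of calls, 143 and 324 would be shared by chance. FIT2 was 5.78 ± 0.24 higher in NFRI 3145 (SE, n = 2 arrays per group, means of 337 and 17961), which may be too small as the latter mean lies above 10000. MAK31, a subunit of an acetyltransferase complex, was at least 17.2-fold higher, and MAL33 at least 25.5-fold higher. FEX2 was at least 152-fold lower, REE1 at least 148-fold lower and PHO3, an acid phosphatase gene, at least 36.0-fold lower. Of the 8 genes named by size in each direction, 7 and 8 stayed called whichever array was left out. Of the cytosolic ribosomal proteins, 81 of 128 were higher and 3 lower (median 0.69, 83 higher and 3 lower adjusted over the list alone, camera adjusted p = 2.7e-19, and adjusted p = 0.48 with an estimated correlation), with RPS28A at 2.75 and RPL37A at 3.38. The value of RPS28A may be too small, as its signal in NFRI 3145 lay above 10000. Of the efflux transporters, 12 of 18 were lower and none higher (median −1.40, 1 higher and 12 lower adjusted over the list alone, camera adjusted p = 8.1e-04, and adjusted p = 0.48 with an estimated correlation), with TPO4 at −4.46 ± 0.23 and RSB1, a lipid transporter gene, at −3.42 ± 0.18.

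Of the histones, 6 of 9 were higher in NFRI 3145 at 0.6% AcOH and none lower (median 0.83, 6 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0058, and adjusted p = 0.67 with an estimated correlation). At 0% AcOH 6 of the 9 were also higher, with a median of 0.87, and the list was not called there (camera adjusted p = 0.21). The difference of the responses of the histones was not called either (camera adjusted p = 0.21). At 0.6% AcOH HTA1, an H2A gene, was 1.16 ± 0.17 higher and HHT2, an H3 gene, 1.56 ± 0.32 higher. With the length trend removed, the histone median was 0.25 and the list was not called (adjusted p = 0.36). In acetate use, glyoxylate cycle and gluconeogenesis, 10 of 20 were lower and 1 higher (median −1.44, or −0.93 with bounds, 1 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.039, and adjusted p = 0.69 with an estimated correlation). PCK1 was −3.64 ± 0.26 apart, the cytosolic acetaldehyde dehydrogenase ALD6 −2.01 ± 0.17 and the acetyl-CoA synthetase ACS2 −1.53 ± 0.14. The acetate list had an adjusted p of 0.18 without NBRC 0224 0.6% AcOH replicate 1, 0.064 and 0.060 without NFRI 3145 0% AcOH replicates 1 and 2, 0.056 and 0.054 without NFRI 3145 0.6% AcOH replicates 1 and 2, and 0.14 with the length trend removed.

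By limma, 676 genes were higher and 1113 lower in NFRI 3145 at 0.6% AcOH, of which 439 and 910 differed at least 2-fold. The split was 847 and 842 after quantile normalization and 1159 and 690 after median centring, with the median difference of all genes at −0.23, −0.02 and 0.26. A group lay below background in 360 of the called genes. Leaving out an array kept each count within 1.5 times its value.

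Of the 6 acid-tolerance genes fixed in advance, HAA1 and PDR12 fell after acid and the other 4 were not called in either response. HAA1 was higher in NFRI 3145 than in NBRC 0224 at 0% AcOH (1.37 ± 0.31 on the log2 scale, SE, n = 2 arrays per group; 188 and 73.4; adjusted p = 0.0035), and no array left out ended that call. After acid HAA1 was at least 4.24-fold lower in NFRI 3145 (adjusted p = 0.0012) and at least 1.91-fold lower in NBRC 0224 (adjusted p = 0.041). The arrays after acid read 38.6 and 45.3 in NFRI 3145, against backgrounds of 43.6 and 39.9, and 33.2 and 31.0 in NBRC 0224, against 31.8 and 43.9, so the size of both falls is not known. The NBRC 0224 call was lost without NBRC 0224 0% AcOH replicate 1 (adjusted p = 0.25) or replicate 2 (0.12), without NBRC 0224 0.6% AcOH replicate 2 (0.093), without NFRI 3145 0% AcOH replicate 1 (0.071) or replicate 2 (0.070), and under both other scalings. PDR12, which exports weak acid anions, was −1.81 ± 0.21 apart between the strains at 0% AcOH (4745 in NBRC 0224 and 1357 in NFRI 3145; adjusted p = 3.7e-05). It fell after acid by 0.91 ± 0.21 in NBRC 0224 (adjusted p = 0.026) and by 0.79 ± 0.21 in NFRI 3145 (adjusted p = 0.032). The PDR12 call in NBRC 0224 was lost without NBRC 0224 0% AcOH replicate 1 (adjusted p = 0.21) or 2 (0.11), NBRC 0224 0.6% AcOH replicate 2 (0.072), or NFRI 3145 0.6% AcOH replicate 1 (0.0503) or 2 (0.0502). The PDR12 call in NFRI 3145 was lost under median centring, and without NBRC 0224 0% AcOH replicate 1 (0.062) or 2 (0.062), NFRI 3145 0% AcOH replicate 1 (0.15) or 2 (0.11), or NFRI 3145 0.6% AcOH replicate 1 (0.21) or 2 (0.087).

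FPS1, the channel through which acetic acid enters the cell, was at least 4.87-fold lower in NFRI 3145 at 0% AcOH, where both groups of NFRI 3145 arrays lay below background. Its change in NBRC 0224 was not called (−1.12 ± 0.34, adjusted p = 0.072). WAR1, the activator of PDR12, was not called in NBRC 0224 (−0.33 ± 0.35), in NFRI 3145 (0.19 ± 0.35) or between the strains (−0.63 ± 0.35). PMA1, the plasma membrane proton pump, was not called either (0.18 ± 0.11, −0.07 ± 0.11 and −0.07 ± 0.11), but its arrays read 14249 to 18856, where a change can be hidden by the top of the scale. Its direction in NFRI 3145 and between the strains turned under median centring, to 0.16 and 0.35. With the length trend removed, PMA1 was called higher in NFRI 3145 at 0% AcOH (0.46, adjusted p = 0.0054). HSP30, which restrains PMA1, was not called in NBRC 0224 (0.70 ± 0.73), in NFRI 3145 (−1.60 ± 0.73) or between the strains (1.48 ± 0.73), and its 2 arrays in NBRC 0224 at 0.6% AcOH read 1063 and 117. The adjusted p of these uncalled changes lay between 0.072 for FPS1 in NBRC 0224 and 0.78 for WAR1 in NFRI 3145.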

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

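The tests of the balance of directions between the strains, the tests of ribosomal protein genes below the top of the scale and against short genes at 0.6% AcOH, and the removal of the trend with gene length were chosen only after the result was seen. The ribosomal protein genes and the balance of directions are strain differences, the genes and lists after them stand out by a tested difference between the strains' responses, and the unnamed probe sets lie outside the comparisons.

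Cytosolic ribosomal protein genes were higher in NFRI 3145 at both acid levels, a list call that is lost with an estimated correlation (adjusted p = 0.58 and 0.48), and the scaling of the arrays is argued against, because the list's median after quantile normalization was 0.58 while 10000 random lists matched on signal gave −0.07 to 0.05. Signals near the top of the scale are argued against as the whole cause, because the 63 members with all 4 group means under 10000 had a median of 1.23 (95% bootstrap interval 0.89 to 1.51), although the 64 members with higher signal lay −0.88 from the other 64, as compression would also give. Loss of 5′ sequence would raise short genes, and such a trend with gene length is argued against as the whole cause at 0.6% AcOH. There the list's 0.76 (0.54 to 1.06) lay above random lists of short genes (0.196 to 0.428). With each array's length trend removed the list stayed called at 0.53. Its 34 members with a short span then gave 0.50 (0.05 to 1.06). At 0% AcOH the trend with gene length cannot be told apart, as the list's 0.58 lay within random lists of short genes (0.269 to 0.594). The list stayed called at 0.38, but its 34 members with a short span gave 0.35 (−0.11 to 0.71). The intervals of these members overlap between the 2 levels, so they do not show that the levels differ. The position of probes along a transcript was not used, so loss of 5′ sequence apart from gene length is not decided at either level. All these bootstrap intervals resample member genes, which are not independent, and do not cover the spread between arrays. A difference in ribosomal protein expression between the strains and probes shared between ribosomal paralogs stay open and were not tested.

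More genes were lower than higher in NFRI 3145, among them GDH2, FEX2 and REE1, and this balance changed with the scaling. The share of called genes that were higher at 0% AcOH was 42.0% as deposited, 51.0% after quantile normalization and 61.6% after median centring, but both scalings shift it by construction, so an origin in the deposited scaling cannot be told apart from a strain difference. Loss of 5′ sequence is a candidate explanation. The lowest 3′ to 5′ ratio on the NFRI 3145 arrays was 3.58 for RIP1 and 8.86 for WBP1, above the highest of the NBRC 0224 arrays at 2.01 and 4.39. Both ends of both genes read lower in NFRI 3145, for RIP1 523 to 644 against 3220 to 4334 at 3′ and 117 to 177 against 1605 to 2410 at 5′. Control probes of the 5′ end that match NFRI 3145 less well would also raise these ratios, which was not tested. The ratio of TDH1 stood apart too (7.68 to 26.5 against 1.59 to 5.11). Its 3′ signal read above 10000 on all NBRC 0224 arrays and on those of NFRI 3145 at 0% AcOH. These TDH1 ratios can be too small, so the size of the gap is not known. ACT1 and all 4 spiked transcripts read above 10000, where ratios can be compressed. Neither the overlap of 4 of them nor the gap of phe (1.23 to 1.32 against 1.07 to 1.19) decides. A strain difference in the number of active genes and probes that do not match NFRI 3145 sequences were not tested and stay open. GDH2, FEX2 and REE1 lay below background in NFRI 3145, where such a mismatch would give the same value as an absent transcript.

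The difference of the responses was −4.81 for YET1, −4.74 for FBP1, −3.91 for YFL064C, −3.65 for PCK1, −3.55 for FRE7, −3.20 for DDR2, −3.19 for HXK1, −3.18 for PRM3 and −1.45 for GLK1. It was 3.33 for FEX2, 3.25 for AZR1, 2.51 for ARG1, 1.95 for TIR4, 1.87 for SCP160, 1.79 for EUG1, 1.52 for HXT1 and 1.42 for ENB1. The lists differed with medians of −1.23 for the general stress (Msn2/4) genes, −1.37 for acetate use, glyoxylate cycle and gluconeogenesis, and 0.39 for amino acid synthesis (Gcn4). None of the 3 was called with an estimated correlation (adjusted p = 0.14, 0.67 and 0.67), and the acetate median was −0.83 (adjusted p = 0.15) without NBRC 0224 0.6% AcOH replicate 1. FEX2, AZR1 and YFL064C lay below background on all NFRI 3145 arrays, so their fitted differences are no measure of a response in that strain, and those of PRM3, YET1 and DDR2 are not exact. With the arrays below background raised to it, their differences were −1.31, −4.31 and −2.70. HXT1 rose to 15381 in NBRC 0224, above 10000, so its smaller response there can be compressed and its difference too large. Of these 17 genes only YET1, FBP1, PCK1 and FRE7 stayed called whichever array was left out, and FBP1 was not called without the variance trend. The other 13 each lost the call without NBRC 0224 0% AcOH replicate 1, most of them without further arrays as well, with adjusted p of up to 0.23 for YFL064C.

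A lower response of the acetate, gluconeogenesis and Msn2/4 genes in NFRI 3145 is a hypothesis. Probes that fail wholly on NFRI 3145 transcripts are argued against for most of the set. Of the 33 genes, 9.09% lay below background on all 4 NFRI 3145 arrays. Probes that match in part can read above background, so this share does not test them and they stay open. Signals near the top of the scale are argued against as the cause for most of the set. In the less responsive strain, 18.2% of the 33 genes had a mean above 10000. For those genes, among them HXT1, HSC82 and RPS28A, compression stays open. Their share is not a low one, as 275 to 315 of the 3879 tested genes read above 10000 on single arrays. A trend with gene length, from loss of 5′ sequence that changed with the treatment, is argued against as the whole cause, because 28 of the 33 genes stayed called with each array's trend removed, which took the Spearman correlation of the difference with gene length from 0.17 to −0.02. Loss of 5′ sequence in single transcripts stays open. The ratios of 3′ to 5′ signal rose with acid for TDH1 (up to 26.5 in NFRI 3145) and by less for WBP1 (up to 9.92). Those of RIP1 overlapped between the acid levels. Compression can add to the rise of TDH1, as its 3′ signal at 0% AcOH lay above 10000. A biological difference between the strains and small differences between cultures that 2 arrays a group cannot resolve stay open too.

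Of the 3470 probe sets without a gene symbol, 436 lay above background on at least 2 arrays. Between the strains at 0% AcOH 55 of them were called higher and 38 lower in NFRI 3145, in NBRC 0224 after acid 7 higher and 5 lower, and in NFRI 3145 after acid 4 and 9. At 0.6% AcOH 39 were higher and 46 lower in NFRI 3145. By limma 0 had a called difference of the responses, with 36 at an unadjusted p under 0.05.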

How the results depend on the processing

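Removal of the gene length trend was chosen only after the result was seen; the other settings were planned. Of 155 called results for named genes, 91 stayed called under every setting run. Every named result still tested kept its side of the threshold among genes above background on all 8 arrays (88 of 88). The same held with every probe set by itself (166 of 166) and without cross-hybridising probe sets (159 of 159). Both of these could change little, because nearly all named genes have a single probe set and the latter drops most genes it affects. Quantile normalization kept 155 of 166, median centring 157, the floor 158, the pseudocount 158, no filter 160, no trend in the variance 126, robust variance 165, the replicate block 163, at least 2-fold 151, adjusted p under 0.01 128, length trend removed 161, and only the groups compared 127 of 149. Leaving out each array in turn kept 1128 of 1314 gene results and 212 of 232 list results. Of 29 list calls, quantile normalization kept 27, median centring 28, the floor 29, the pseudocount 28, no filter 29, genes above background on all arrays 25, no trend 26, the block 28, length trend removed 25, fry 20, and only the groups compared 24 of 26. The list test takes no robust variance, which was not run there, and only the groups compared was not run for the difference of the responses.

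Where counts moved, the cause was not tested unless stated. Without a filter, lists called between the strains were 5 at 0% AcOH and 7 at 0.6%. Among genes above background on all 8 arrays, which are fewer, 194 were lower in NFRI 3145 after acid and 16 had a higher response there. Genes with a higher response were 15 after quantile normalization, 19 after median centring, 13 with the floor and 13 with the block, and with the pseudocount 36 higher and 95 lower. Quantile normalization gave 4 and 7 lists between the strains. Median centring gave 335 higher after acid in NFRI 3145, 1347 higher between the strains at 0% AcOH, and 1159 higher and 690 lower at 0.6%. Without the variance trend, NBRC 0224 had 36 and 68, NFRI 3145 73 higher, the shared calls 59, and the difference 0 higher (251 at an unadjusted p under 0.05 by limma) and 5 lower. With only the groups compared, which leaves fewer arrays, these were 55 and 87, 246, and 84 shared. At least 2-fold left 90 higher in NBRC 0224, 69 in NFRI 3145, and 543 and 439 between the strains. An adjusted p under 0.01 left 50 and 60, 41 and 166, 1 and 6 for the difference, and 46 shared. With an estimated correlation camera called 0 lists in each comparison (5, 6, 2, 3 and 2 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 24 and 25 between the strains and 1 for the difference. With the length trend removed, 1 and 2 lists were called between the strains. Median centring shifts all genes of a comparison alike and moved these medians of called lists by more than 1.5 times: in NBRC 0224 Msn2/4 to 0.36, ribosomal proteins to 0.30, glycolysis to 0.31, the respiratory chain to 0.29, Gcn4 to −0.05 and oxidative stress to 0.34, and in NFRI 3145 Msn2/4 to −0.38, zinc to −0.15 and the respiratory chain to 0.60. Between the strains it gave 1.15 and 1.18 for ribosomal proteins at 0% and 0.6% AcOH, and at 0.6% AcOH −0.91 for efflux, −0.95 for acetate use and 1.32 for histones. Quantile normalization gave 0.34 for Msn2/4, 0.05 for ribosomal proteins and 0.28 for the respiratory chain in NBRC 0224.

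These directions reversed, and the cause was not tested: FPS1 in NFRI 3145, to 0.21 after quantile normalization and 0.0315 without NFRI 3145 0.6% AcOH replicate 1 (leaving out each array gave −0.55 to 0.0315); the glycolysis list in NBRC 0224, to −0.0070 after quantile normalization; PMA1 under median centring, to 0.16 in NFRI 3145 and 0.35 between the strains at 0% AcOH, and 0.46 there with the length trend removed, where it was called (adjusted p = 0.0054); FEX2 in the difference, to −0.16 with the floor and −0.21 with the pseudocount; HSP30 in NBRC 0224, to −0.89 without NBRC 0224 0.6% AcOH replicate 1 (−0.89 to 2.30); and WAR1 in NFRI 3145, to −0.10 without NFRI 3145 0% AcOH replicate 2 (−0.10 to 0.49). Leaving out each array gave 44 to 325 higher and 32 to 425 lower in NBRC 0224, 42 to 251 and 126 to 514 in NFRI 3145, 563 to 992 and 863 to 1208 between the strains at 0% AcOH, 452 to 683 and 865 to 1116 at 0.6%, 0 to 169 and 5 to 174 for the difference, and 41 to 224 shared. Lists called were 9 to 12, 8 to 10, 2 to 2, 3 to 4 and 3 to 5. Correlations of the replicate deviations between groups ran from −0.05 to 0.05 over 6 pairs of groups, so the numbers pair no arrays by this measure. Genes near the background of 31.5 to 43.9 intensity units carry the least precise changes.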

Other observations

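Genes of this part were chosen after their values were seen, except in the tests of neighbouring genes and of chromosomes, which were planned before their results. Some genes that respond to low oxygen fell in both strains after acid. HEM13, an enzyme of heme synthesis, changed by −2.26 ± 0.17 in NBRC 0224 (SE, n = 2 arrays per group; 12319 to 2592) and by −1.81 ± 0.17 in NFRI 3145 (8306 to 2372). AAC3, a mitochondrial ADP/ATP carrier of anaerobic growth, changed by −1.44 ± 0.18 and −1.49 ± 0.18. The cell wall mannoprotein gene TIR4 changed by −2.72 ± 0.20 and −0.76 ± 0.20, and TIR1 by −0.55 ± 0.13 (16679 to 11414, both above 10000, where a change can be compressed) and −2.06 ± 0.13 (8183 to 1958). Of the 21 tested anaerobic and hypoxic genes, 5 fell in NBRC 0224 and 6 in NFRI 3145, the list's medians were −0.09 and −0.11, and the list was not called (camera adjusted p of 0.057 and 0.088). Among hexose transporters, HXT1 rose by 1.39 ± 0.17 (to 15381, so this value may be too small) and 2.91 ± 0.17. The high-affinity transporter gene HXT4 changed by −1.56 ± 0.24 and −2.94 ± 0.24. The falls of HEM13 and HXT4 in NBRC 0224 start above 10000 and may be too small in size as well.

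Chromosome XIV carried a higher signal in NFRI 3145 than in NBRC 0224. This may reflect a gain of the chromosome in NFRI 3145 or a loss in NBRC 0224, hypotheses that need a measurement of DNA. The median strain difference of its 277 tested genes exceeded that of the other genes by 0.39 at 0% AcOH and 0.40 at 0.6% AcOH after quantile normalization, above the 0.3 set before as a threshold (adjusted p = 0.0016 at both levels, permutation p = 1e-04, the smallest these permutations can give). The other 15 chromosomes departed by at most 0.27 and 0.29 in size. The departure was 0.31 to 0.37 on each of the 4 NFRI 3145 arrays and −0.03 to 0.02 on the 4 NBRC 0224 arrays. These values compare the strains and do not tell which of them departed. The departure was 0.36 and 0.33 in the deposited scaling and 0.29 and 0.39 with the length trend removed, where the 0.29 at 0% AcOH lies under the threshold. Of the chromosome's genes, 61.0% lay above the other genes' median at 0% AcOH. The permutations move genes and do not cover the spread between arrays. At 0% AcOH, 4 successive parts of the chromosome with 69 or 70 genes each gave 0.14, 0.41, 0.24 and 0.54.

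Counted over all placed genes, adjacent pairs with large strain differences were not more frequent than permutations gave. This count does not test single runs. At 0% AcOH, 204 genes were at least 4-fold higher and 508 at least 4-fold lower in NFRI 3145, and 85 pairs of adjacent tested genes differed this much in the same direction. Permuting the differences over genes gave a median of 77 and at most 106 pairs (permutation p = 0.2). The 13 runs of 3 or more such neighbours held 43 genes. The longest, of 5 genes each, were GEF1 to TAH11 and VTS1 to PIP2, both lower in NFRI 3145. GEF1 to TAH11 holds the mitochondrial chaperone gene SSC1 (6955 in NBRC 0224 and 354 in NFRI 3145). THR4 to PWP2 holds the threonine synthase gene THR4 (6868 and 402). AGP3, DAK2 and ZNF1 form a run higher in NFRI 3145, with all 3 below background in NBRC 0224. Whether such runs exceed chance was not tested.

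Of the 7 control probe sets for ribosomal RNA, all had a lower mean after acid in NFRI 3145, by 1.12-fold to 14.2-fold, and 5 in NBRC 0224. PolyA RNA was prepared, so these signals also depend on how much ribosomal RNA each preparation carried over. They do not measure its level in the cells. At 0% AcOH the means of 5.8S and of the 3′ end of 25S lay above 10000, where a change can be compressed. The mean of 5.8S went from 19733 to 1583 in NBRC 0224 and from 25354 to 8551 in NFRI 3145, where the arrays read 12534 and 4568. That of the middle of 25S went from 1090 to 381 and from 4179 to 290, and that of the middle of 18S from 244 to 399 and from 735 to 375. All 4 spiked transcripts read highest on NBRC 0224 0.6% AcOH replicate 2, lys at 21669 against 11876 to 14799 on the other arrays, phe at 27255 against 17496 to 20142, dap at 30306 against 23123 to 27357 and thr at 25293 against 17716 to 21028.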
